A study of Mus musculus with 12 samples.

How the data were processed

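RNA from primary mouse hepatocytes was measured by poly-A RNA sequencing in 12 libraries, 3 in each of 4 groups. The cells came from a wild-type C57BL/6J animal, were plated after collagenase perfusion, and were kept without serum for 16 h overnight. The Mock group received no hormone mimic. The FD group received 10 µM forskolin, an activator of adenylate cyclase that raises cAMP, and 1 µM dexamethasone, a synthetic glucocorticoid, for 5 h before lysis. The FDI group received the same with 100 nM insulin added 1 h earlier, and the FDMn group received the same after the 16 h with 6 µM manganese chloride. Group and replicate number were taken from the sample titles, and each column of the table was matched to its sample by the library name in the sample's description. The labels speak of a single animal and do not say whether replicates are separate preparations. The p-values therefore measure the spread between these samples, which may be technical.

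The authors deposited one table of gene-level TPM (transcript abundance scaled to a fixed total) for all 12 libraries, with 36144 gene symbols and no column left unused. Per the submitters' processing notes, kallisto 0.44.0 and the mouse build GRCm38.p6 were used, and DESeq2 is named without its role. The annotation release, the filters, the use of strand and the way transcripts were summed to genes are not given in the sources used here. Reads from a gene and from an antisense or overlapping partner can therefore not be told apart. Each deposited TPM column sums to 1000000, so a value is a share of the library's transcripts, and a rise in abundant transcripts lowers every other value. TPM keeps no record of the number of reads. The depth per sample is therefore unknown, no counting interval or detection floor is given, and a value of 0 means only that the gene is listed at 0. Symbols were matched to GENCODE M21, an annotation of GRCm38, for coordinates; 36003 symbols (99.6%) had a gene of the same name.

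Genes with a TPM of at least 1 in at least 3 of the 12 samples were kept, 11544 in all, of which 11062 are annotated as protein-coding. The values were analysed as log2(TPM + 1), and every log2 change below is on that scale, which understates the change of genes with low values. Ratios of group mean TPM are given as folds. A linear model with 1 term per group was fitted over all 12 samples with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 4 comparisons were FD with Mock, FDMn with FD, FDI with FD, and FDMn with FDI. The last is the direct test of whether FDMn and FDI differ. Manganese was given for the 16 h before forskolin and dexamethasone, and insulin for 1 h before them. The comparison therefore cannot separate the agent from the length of exposure. No group received manganese or insulin without forskolin and dexamethasone. A reversal of the FD response thus cannot be told apart from a change that either agent makes by itself.

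A set of 27 gene lists was tested with camera from limma, using a preset correlation of 0.01 between genes and adjustment over the lists. The same test with a correlation estimated from the data, and the rotation test fry, were run beside it. Camera compares a list with the other genes, while fry asks whether its own members moved. Some genes belong to more than 1 list, so the list calls are not independent of each other. A list said below not to pass is one that did not pass camera, and several such lists passed fry. For each list, members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. Where these counts are equal, 1 is given. The lists, the model, the filter and the alternatives described in the closing part were fixed before the data were examined, except where said otherwise.

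Genes are named by a rule fixed in the same way. It takes 13 genes of glucose, insulin and metal biology, the 6 highest and 6 lowest log2 changes per comparison among genes past the threshold, and up to 4 members of each list with the smallest adjusted p. The highest and lowest genes also needed a mean TPM of at least 5 in at least 1 of the groups compared and no overlap between their replicates, and predicted genes and pseudogenes were left out. Genes named outside this rule are said to be chosen after their values were seen. A few genes that the rule takes are not reported here.

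The fit was tested on simulated data with 200 of the 11544 genes changed by known folds. All 4 simulations gave every group the same mean per gene and the same fitted spread, with independent normal noise. Differences between the 4 sets of shares below therefore come from the random draw and do not describe the real comparisons. In the simulated FD and Mock comparison it recovered 62.3% of the 1.5-fold, 90.5% of the 2-fold and 97.1% of the 4-fold changes, with 5.1% of its calls false. For FDMn with FD the shares were 73.3%, 94.6% and 98.5%, with 6.8% of calls false. For FDI with FD they were 70.6%, 89.6% and 100.0%, with 7.0% of calls false, and for FDMn with FDI 55.1%, 87.0% and 100.0%, with 1.9% of calls false.

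FDMn and FDI were both compared with the same 3 FD libraries, which also define the FD response. The values that shared libraries give with no effect of manganese or insulin were simulated in 100 draws, using each gene's fitted spread and each group's relative spread. The FD group of 3 cannot be divided into parts of at least 2 libraries each. As a test chosen after seeing the data, 1 FD library was used to define the FD response, or for one of the effects, and the other 2 for the comparison with FDMn or FDI. Alternatives tried were a pseudocount of 0.1, no filter, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, leaving out mitochondrially encoded genes, a prior without trend, a robust prior, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. Sample quality weights, and leaving out FD replicates 1 and 2, were added after seeing the data.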

Results

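Gene expression was profiled in 12 libraries of cultured primary mouse hepatocytes, 3 each of untreated cells (Mock), cells given forskolin and dexamethasone to imitate the fasting hormones (FD), FD cells also given insulin (FDI), and FD cells also given manganese (FDMn). Between 10900 and 11161 genes per library had a TPM of at least 1. Albumin (Alb) ranged from 22527 to 32589 TPM over the libraries. Replicates correlated across genes with r from 0.983 to 0.986 in Mock, 0.981 to 0.983 in FD, 0.989 to 0.991 in FDI and 0.989 to 0.991 in FDMn; genes are not independent replicates. The first principal component held 45.3% of the variance and separated Mock from the other groups. The second held 12.4%, and FD replicates 1 and 2 (scores of 22.3 and 29.0) lay farther out on it than FD replicate 3 (7.98).

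The first comparison asked what forskolin and dexamethasone change in hepatocytes. Genes of glucose production and amino acid breakdown were among those that rose most. Pck1, the rate-controlling enzyme of gluconeogenesis, went from 0.343 ± 0.171 TPM in Mock to 337 ± 37.1 TPM in FD (SD, n = 3 each), a log2 change of 7.98 ± 0.10 (SE, adjusted p = 1.5e-13). Tat, which breaks down tyrosine, rose 98.2-fold to 757 ± 106 TPM. G6pc, the catalytic subunit of glucose-6-phosphatase, rose from 0.257 ± 0.179 to 30.8 ± 4.08 TPM. Cps1, the first enzyme of the urea cycle, rose from 3.76 ± 0.714 to 207 ± 29.9 TPM, the kinase gene Sgk1 34.9-fold and the lysine-degrading Aass 25.6-fold. These were the 6 highest changes under the naming rule, each with no overlap between the replicates of the groups.

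On the GRCm38 assembly Pck1 lies on chromosome 2 (173153048 to 173159273), G6pc on chromosome 11 (101367561 to 101377903), Tat on chromosome 8 (109990437 to 109999803) and Igfbp1 on chromosome 11 (7197782 to 7202546), and all 4 are annotated as protein-coding. Igfbp1, a secreted IGF-binding protein that insulin represses, rose 10.5-fold to 282 ± 35.5 TPM (log2 change 3.35 ± 0.12, adjusted p = 6e-10). The coactivator Ppargc1a rose 25.5-fold to 20.2 ± 3.10 TPM and the insulin receptor substrate Irs2 4.46-fold to 14.1 ± 0.808 TPM. The metallothioneins Mt1 and Mt2 rose 5.66-fold and 6.08-fold, and the zinc and manganese importer Slc39a14 4.23-fold. Srebf1 (log2 change −0.26 ± 0.23, adjusted p = 0.39) and Fasn (0.04 ± 0.14, adjusted p = 0.85), genes of fat synthesis, did not pass the test. The manganese exporter Slc30a10 stayed below the filter, with 0.011 to 0.084 TPM in Mock libraries and 0.210 to 0.338 TPM in FD libraries.

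The lists of fasting hormone targets rose as groups. Of 16 measured gluconeogenic genes, 14 rose and 2 fell (median log2 change 1.76, camera adjusted p = 1.17e-13). Got1 rose 8.93-fold and Gpt2 4.02-fold. Of 20 cAMP and CREB targets, 17 rose and 1 fell (17 and 2 adjusted over the list alone), with Nr4a3 up 38.6-fold and Per1 6.96-fold (camera adjusted p = 5.41e-17). Of 21 glucocorticoid receptor targets, 18 rose and 1 fell, with Tsc22d3 up 6.09-fold (camera adjusted p = 2.87e-23). Of 23 genes of amino acid catabolism and the urea cycle, 18 rose (19 adjusted over the list alone) and the rest did not pass the test (camera adjusted p = 5.16e-21). Of 21 FOXO targets, 16 rose and 4 fell, including Klf15, up 15.5-fold (camera adjusted p = 3.03e-10). Of 20 genes of glycolysis and glycogen, 14 rose and 1 fell (camera adjusted p = 3.03e-10). The glycogen-targeting subunit Ppp1r3c rose 7.27-fold. Of 23 HIF targets, 21 rose and 1 fell (22 and 1 adjusted over the list alone, camera adjusted p = 5.81e-18). Vegfa rose 3.25-fold and Pfkfb3 6.15-fold. These 7 calls also passed with an estimated correlation, at adjusted p from 0.000365 to 0.0433. They are not independent, because the lists share members. Pck1 and Ppargc1a are in the gluconeogenic, cAMP and FOXO lists, and G6pc is in the gluconeogenic and FOXO lists. Tat is in the gluconeogenic, glucocorticoid receptor and amino acid lists.

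The 6 lowest changes were the chemokine Cxcl10, which fell from 19.8 ± 0.247 to 1.35 ± 1.01 TPM, Sox4, Il1rn, Cachd1, Eepd1 and Il34. Sox4, a transcription factor gene, fell from 49.9 ± 1.96 to 5.32 ± 0.675 TPM (log2 change −3.01 ± 0.09, adjusted p = 1.9e-10). Of 21 ribosome biogenesis genes, 18 fell and 1 rose (19 and 1 adjusted over the list alone), with Nop56 going from 188 ± 5.66 to 106 ± 1.08 TPM and Myc from 184 ± 13.2 to 103 ± 1.87 TPM (camera adjusted p = 4.51e-05, and 0.0433 with an estimated correlation). All 4 measured cholangiocyte marker genes fell, among them Cldn4, from 176 ± 17.7 to 61.4 ± 6.00 TPM (camera adjusted p = 0.00198; adjusted p = 0.077 with an estimated correlation). Of 20 integrated stress response genes, 11 fell and 3 rose (11 and 4 adjusted over the list alone), but the list as a whole did not pass the camera test (adjusted p = 0.169). It did pass fry, with the direction down (fry adjusted p = 0.000676). The hepatocyte factor Hnf4a rose 3.94-fold. Of 20 hepatocyte identity genes 7 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.000156; adjusted p = 0.211 with an estimated correlation).

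In fatty acid oxidation 5 of 24 genes rose and 4 fell, with Cpt1a, the entry enzyme of the pathway, up 8.09-fold and Plin2 falling from 530 ± 14.5 to 184 ± 33.4 TPM (camera adjusted p = 0.00611; adjusted p = 0.211 with an estimated correlation). In the bile acid list 5 of 21 rose and 4 fell (camera adjusted p = 0.00802; adjusted p = 0.211 with an estimated correlation). In the acute phase list 8 of 22 rose and 2 fell (camera adjusted p = 0.000195; adjusted p = 0.154 with an estimated correlation), and in the mitochondrially encoded list 5 of 13 rose and 1 fell (camera adjusted p = 0.00118; adjusted p = 0.401 with an estimated correlation). In cholesterol synthesis 6 of 25 rose and 12 fell, in fatty acid synthesis 3 of 18 rose and 7 fell, and in the insulin signalling list 7 of 21 rose and 8 fell, Foxo1 rising 4.25-fold; none of these 3 lists passed camera (adjusted p = 0.974, 0.974 and 0.271). The NRF2 (3 of 23 rose, 6 fell), unfolded protein response (3 of 19 rose, 5 fell) and interferon (2 of 22 rose, 6 fell) lists did not pass either, at adjusted p = 0.974, 0.408 and 0.653. Gclc, which limits glutathione synthesis, rose 8.44-fold and the NRF2 target Osgin1 fell from 1253 ± 213 to 369 ± 36.5 TPM. Of 23 genes of metal handling 7 rose and 8 fell (7 and 9 adjusted over the list alone, camera adjusted p = 0.0667), and of 11 proliferation genes 1 rose and 6 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.169). Of the markers of other cells, 2 of 10 endothelial genes rose and 5 fell (3 and 6 adjusted over the list alone), and 1 of 5 stellate cell genes rose and 2 fell. The endothelial, stellate, Kupffer cell and lymphocyte lists had camera adjusted p = 0.990, 0.974, 0.408 and 0.961. The median and the camera direction differed in sign for the insulin signalling, fatty acid synthesis, cholesterol, metal, unfolded protein response, NRF2 and endothelial lists (medians below 0, direction up), and the mean was above 0 for the insulin signalling, cholesterol, metal and NRF2 lists.

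In all, 1296 genes were higher and 3447 lower in FD than in Mock, of which 370 and 429 changed at least 2-fold. The replicates of the groups did not overlap for 48.0% of genes, against 10% by chance. The balance of directions depended on scaling: the median log2 change of all genes was −0.15 on TPM and −0.01 after median-of-ratios scaling, which gave 2054 higher and 1982 lower, so that lower genes went from 72.7% to 49.1% of the calls. Quantile normalization gave 2178 lower genes. Under median-of-ratios scaling 12 rather than 18 ribosome biogenesis genes and 6 rather than 12 cholesterol synthesis genes fell, and 14 rather than 7 hepatocyte identity genes rose. It also gave 17 rather than 8 acute phase genes, 11 rather than 5 mitochondrially encoded genes, 8 rather than 3 unfolded protein response genes and 9 rather than 5 fatty acid oxidation genes that rose. Fewer genes fell in the metal (4 rather than 8), fatty acid synthesis (4 rather than 7), interferon (3 rather than 6), unfolded protein response (3 rather than 5), bile acid (2 rather than 4) and fatty acid oxidation (2 rather than 4) lists. Quantile normalization gave 7 acute phase, 4 mitochondrially encoded, 7 hepatocyte identity, 5 unfolded protein response and 8 fatty acid oxidation genes that rose. With it 4 rather than 8 insulin signalling genes fell (6 with median-of-ratios scaling), and 5 metal, 4 interferon, 3 unfolded protein response, 2 bile acid and 2 fatty acid oxidation genes fell.

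**Figure D1:**
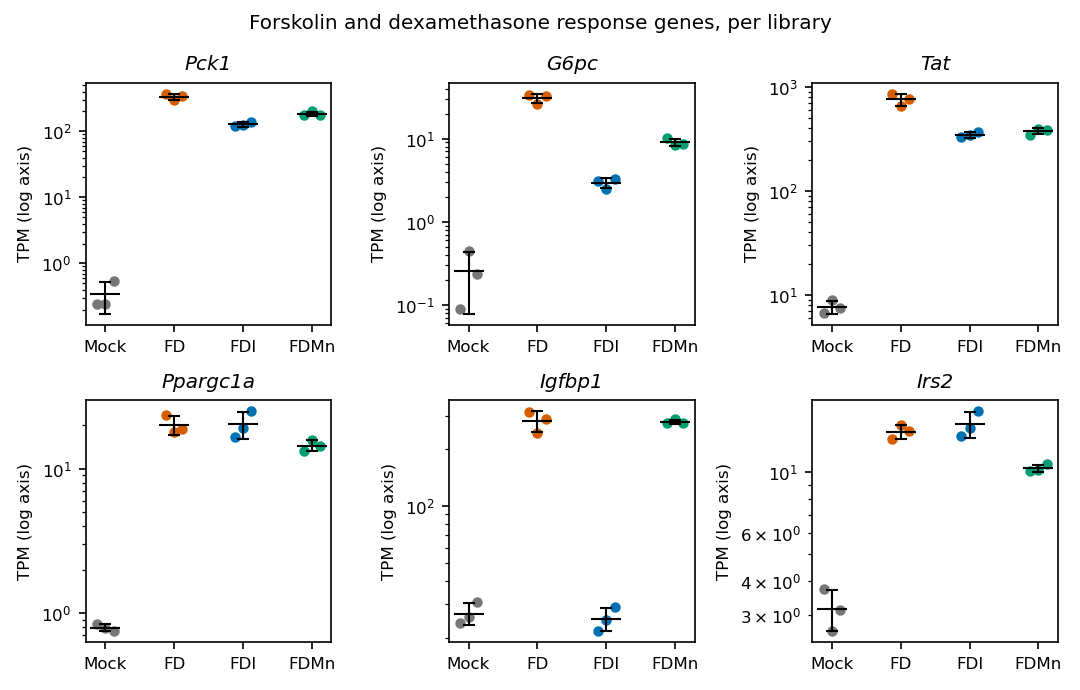
TPM on log axes for Pck1, G6pc, Tat, Ppargc1a, Igfbp1 and Irs2 in the 4 groups; points are libraries, and bars show the mean ± SD of 3. Igfbp1 in FDI lies at 25.2 TPM, close to the 26.8 TPM of Mock, while in FDMn it lies at 278 TPM, near the 282 TPM of FD.

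The second comparison asked what manganese changes in cells given forskolin and dexamethasone. Several FD-raised genes of glucose production fell with manganese. G6pc fell from 30.8 ± 4.08 TPM in FD to 9.06 ± 0.937 TPM in FDMn (log2 change −1.66 ± 0.14, adjusted p = 2.1e-05, n = 3 each), Tat from 757 ± 106 to 374 ± 24.8 TPM (−1.01 ± 0.11, adjusted p = 0.00011), and Pck1 from 337 ± 37.1 to 185 ± 12.8 TPM (−0.86 ± 0.10, adjusted p = 0.00025). Igfbp1 was at 278 ± 7.33 TPM with manganese (−0.01 ± 0.12, adjusted p = 0.96). Ppargc1a was at 14.5 ± 1.24 against 20.2 ± 3.10 TPM and missed the threshold (adjusted p = 0.057), and Irs2 fell to 10.4 ± 0.32 TPM (adjusted p = 0.028). The Irs2 call ended without FD replicate 2 or 3, without any single FDMn replicate, with no filter on low values, and with 1 FD library.

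Of the 16 gluconeogenic genes, 6 fell and 2 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.00331; adjusted p = 0.281 with an estimated correlation). Of 23 genes of amino acid catabolism and the urea cycle, 14 fell (15, with 1 that rose, adjusted over the list alone), with Cps1 going from 207 ± 29.9 to 79.7 ± 2.94 TPM and Aass from 169 ± 9.17 to 110 ± 4.32 TPM (camera adjusted p = 1.82e-07; adjusted p = 0.0812 with an estimated correlation). Of 21 FOXO targets, 11 fell and 2 rose (13 and 3 adjusted over the list alone, camera adjusted p = 0.000334; adjusted p = 0.137 with an estimated correlation). Txnip fell from 4.75 ± 0.562 to 1.88 ± 0.359 TPM and the growth arrest gene Gadd45a rose 3.28-fold. Of 21 glucocorticoid receptor targets, 8 fell and 2 rose (camera adjusted p = 0.00376, and 0.152 with an estimated correlation). Of these, glutamine synthetase (Glul), a manganese-binding enzyme, went from 42.8 ± 5.13 to 14.8 ± 2.03 TPM. Glul also fell with insulin (FDI against FD, log2 change −1.11, adjusted p = 0.000127). The cAMP and CREB list split, with 6 of 20 rising and 7 falling (7 and 10 adjusted over the list alone, camera adjusted p = 0.493): the immediate-early genes Fos and Fosb rose 3.69-fold and 3.34-fold, while Ppp1r3c fell from 8.66 ± 1.25 to 3.34 ± 0.501 TPM.

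Hamp, which encodes the iron hormone hepcidin, rose 3.74-fold to 44.3 ± 3.94 TPM and the transferrin receptor Tfrc 2.90-fold to 40.1 ± 6.09 TPM (adjusted p = 4.7e-06 and 1.5e-05). The zinc importer Slc39a4 rose 1.89-fold. Mt1 fell from 5122 to 3855 TPM (log2 change −0.41 ± 0.06, adjusted p = 0.0011), Mt2 was at 1770 against 1875 TPM (adjusted p = 0.65), and Slc39a14 rose 1.24-fold (adjusted p = 0.047). The Mt1 call ended with quantile normalization, and the Slc39a14 call in 12 of its alternatives, among them every one that left out an FDMn replicate, FD replicate 1 or FD replicate 2. Of the 23 measured genes of manganese and other metal handling, 8 rose and 6 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.397). Hmox1, which degrades heme, fell from 217 ± 63.8 to 75.6 ± 7.29 TPM. It belongs to the NRF2 list, of which 8 of 23 fell and 2 rose (10 and 3 adjusted over the list alone), with Gstm3 falling from 84.3 ± 2.30 to 39.7 ± 1.96 TPM (camera adjusted p = 0.00331; adjusted p = 0.137 with an estimated correlation).

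The integrated stress response rose with manganese, with 14 of 20 genes higher (17 adjusted over the list alone, median log2 change 0.46, camera adjusted p = 9.16e-12, and 0.0812 with an estimated correlation). The summed TPM of the list was 1675 ± 107 in Mock, 1290 ± 11.9 in FD and 1837 ± 51.0 in FDMn. Much of the rise thus offset the lower level in FD. Ddit3 rose 2.94-fold to 38.6 ± 2.45 TPM, Trib3 2.84-fold and Mthfd2 2.01-fold. Of the unfolded protein response list 8 of 19 fell and 2 rose (10 and 3 adjusted over the list alone), with the chaperone genes Calr going from 1081 ± 83.6 to 569 ± 46.6 TPM and Hsp90b1 from 245 ± 13.6 to 152 ± 5.46 TPM (camera adjusted p = 0.00568; adjusted p = 0.137 with an estimated correlation). Of 22 acute phase genes 10 rose and 1 fell, with Lcn2 up 2.20-fold and the fibrinogen genes Fgb and Fgg up 1.54-fold and 1.69-fold (camera adjusted p = 2.06e-06; adjusted p = 0.137 with an estimated correlation). Of 22 interferon response genes 6 rose (7, with 2 that fell, adjusted over the list alone), Isg15 1.73-fold (camera adjusted p = 0.0105; adjusted p = 0.403 with an estimated correlation). Of 11 proliferation genes 4 fell, the replication genes Mcm2, Mcm3, Mcm5 and Mcm6 (camera adjusted p = 0.0477; adjusted p = 0.142 with an estimated correlation). Of 21 ribosome biogenesis genes 4 rose, Nop56 1.18-fold (camera adjusted p = 0.00693; adjusted p = 0.152 with an estimated correlation).

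The 6 lowest genes with manganese included the contractile genes Myl9, from 14.5 ± 1.74 to 2.36 ± 0.656 TPM, Cnn1, with a log2 change of −2.17 to 1.84 ± 0.494 TPM, and Acta1, from 13.0 ± 1.56 to 3.50 ± 1.32 TPM, together with Selenbp2, Fmo2 and G6pc. The 6 highest were Lce1d, Hamp, Nupr1, Gadd45a, Emp1 and Ctsw. The stress-induced Nupr1 rose 3.48-fold to 32.6 ± 0.615 TPM. In the stellate cell and fibroblast list Tagln and Acta2, which encode contractile proteins, fell (camera adjusted p = 0.0328; adjusted p = 0.137 with an estimated correlation), while Dcn (2.87 against 2.83 TPM, adjusted p = 0.97) and Sparc (4.08 against 4.79 TPM, adjusted p = 0.73) did not pass. Among markers of other cells, Cd68, also a lysosomal membrane protein, rose 2.28-fold to 794 ± 43.4 TPM, Spp1 2.08-fold and Sox9 1.48-fold, and the macrophage gene C1qb was at 2.26 ± 0.985 against 1.25 ± 0.496 TPM (adjusted p = 0.29). Of 4 cholangiocyte genes 2 rose (2 rose and 2 fell adjusted over the list alone). The Kupffer cell, endothelial and cholangiocyte lists did not pass camera (adjusted p = 0.124, 0.174 and 0.214). The interferon call ended without FDMn replicate 2, the stellate call without FD replicate 3 and in a fit of only the 2 groups, and the proliferation call in 10 of its alternatives, among them those without FD replicate 1, FD replicate 3 or FDMn replicate 2. In fatty acid oxidation 4 of 24 genes rose and 6 fell (4 and 9 adjusted over the list alone), in fatty acid synthesis 1 of 18 rose and 4 fell (2 and 4), in the bile acid list 3 of 21 rose and 5 fell (4 and 5), in cholesterol synthesis 5 of 25 rose and 2 fell (7 and 4), and in glycolysis and glycogen 3 of 20 rose and 4 fell. None of these lists passed camera (adjusted p = 0.112, 0.112, 0.876, 0.594 and 0.397). The HIF list, with 3 of 23 rising and 1 falling, had a median of −0.05, a mean of 0.04 and the direction up (camera adjusted p = 0.781).

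**Figure D2:**
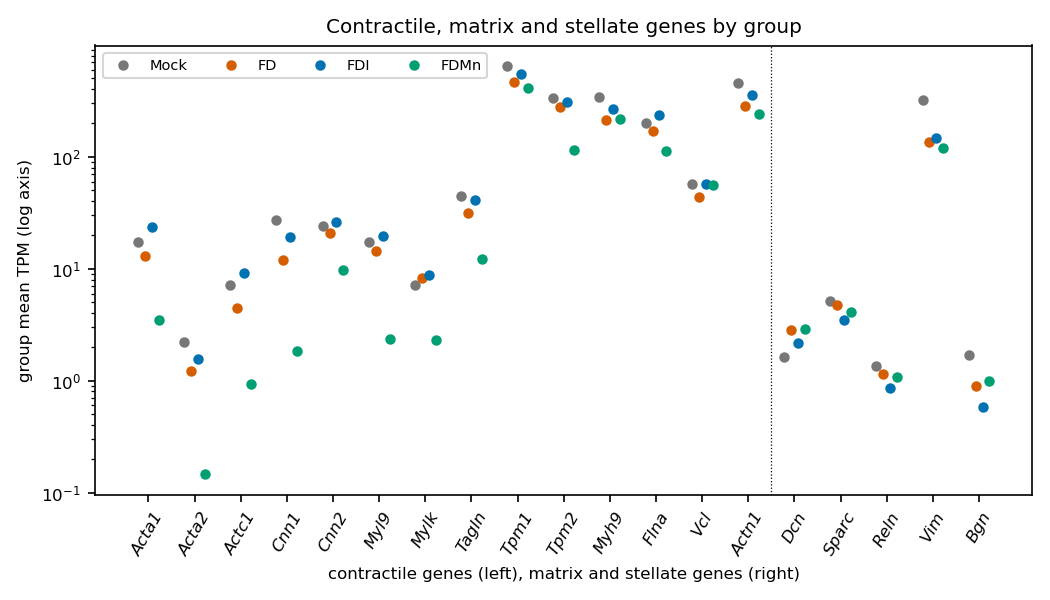
Group mean TPM (log axis) of 14 contractile genes, left of the dotted line, and 5 matrix or stellate cell genes, right of it, in the 4 groups; points are means of 3 libraries without error bars, and the gene set was chosen after values were seen. Tagln has a mean of 12.1 TPM in FDMn and 31.2 TPM in FD, and Sparc 4.08 and 4.79 TPM.

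Manganese left 834 genes higher and 912 lower than FD alone, of which 72 and 51 changed at least 2-fold, and 33.0% of genes had replicates that did not overlap, against 10% by chance. Without FDMn replicate 1 the counts were 475 and 540, without FDMn replicate 2 the higher count was 536, and with FD replicate 3 as the only FD library they were 293 and 338 and the calls of Isg15, Mcm2 and Sox9 ended. Selenbp2, the metallothioneins and the actin genes have close relatives whose reads the authors' counting may have divided, so their values are less certain.

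**Figure D3:**
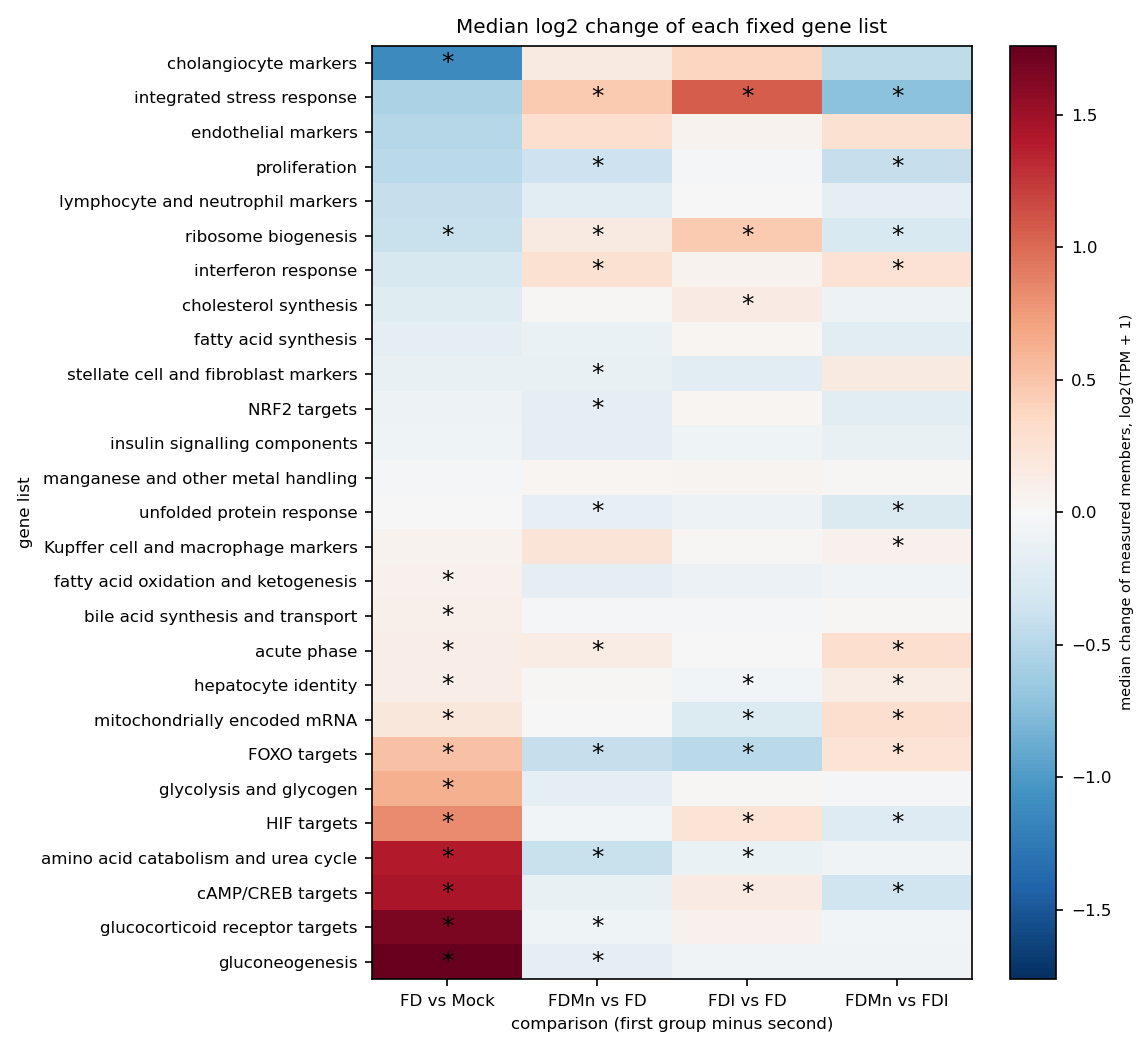
Median log2 change of the measured members of each of the 27 gene lists (colour, on log2(TPM + 1)) in the 4 comparisons; a star marks a camera adjusted p under 0.05 with the preset correlation. The integrated stress response list has medians of −0.56, 0.46, 1.07 and −0.72 from left to right.

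The third comparison asked what insulin changes in cells given forskolin and dexamethasone. Igfbp1 fell from 282 ± 35.5 to 25.2 ± 3.60 TPM (log2 change −3.44 ± 0.12, adjusted p = 2e-08, n = 3 each) and G6pc from 30.8 ± 4.08 to 2.96 ± 0.421 TPM (−3.00 ± 0.14, adjusted p = 3.7e-07). Pck1 fell to 127 ± 9.33 TPM (−1.40 ± 0.10, adjusted p = 4.5e-06) and Tat to 346 ± 21.9 TPM (−1.12 ± 0.11, adjusted p = 3.8e-05). Ppargc1a was at 20.4 ± 4.34 against 20.2 ± 3.10 TPM (adjusted p = 0.99), and Irs2 (adjusted p = 0.69), Srebf1 (adjusted p = 0.44) and Fasn (adjusted p = 0.19) did not pass the test either.

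Of 21 FOXO targets, 10 fell and 2 rose with insulin (13 and 2 adjusted over the list alone, camera adjusted p = 3.5e-09, and 0.0315 with an estimated correlation). Ccng2 fell from 30.8 ± 2.16 to 8.38 ± 0.577 TPM. In amino acid catabolism and the urea cycle 6 of 23 fell and 1 rose (camera adjusted p = 1.74e-05; adjusted p = 0.0827 with an estimated correlation), with Cps1 going from 207 ± 29.9 to 34.8 ± 4.18 TPM and Tdo2, the tryptophan dioxygenase, from 100.5 ± 8.95 to 20.1 ± 2.52 TPM. Sgk1 fell to 126 ± 15.7 TPM, though the glucocorticoid receptor list had 5 of 21 rising and 6 falling (7 and 6 adjusted over the list alone, camera adjusted p = 0.388). The 16 gluconeogenic genes had 3 rising and 3 falling (3 and 4 adjusted over the list alone, camera adjusted p = 0.244). The other genes among the 6 lowest were Sorbs3 and Klhl24.

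The integrated stress response rose most with insulin: 19 of 20 genes were higher (median log2 change 1.07, camera adjusted p = 2.08e-22, and 0.0121 with an estimated correlation). Ddit3 rose 6.25-fold to 82.2 ± 5.15 TPM, Trib3 5.18-fold to 112 ± 16.8 TPM, and Chac1, a glutathione-degrading enzyme, 4.59-fold to 73.7 ± 6.91 TPM. These 3, with Gadd45a, Fhl2 and the amino acid transporter Slc7a1, were the 6 highest under the naming rule. Of 21 ribosome biogenesis genes, 17 rose (18 adjusted over the list alone, camera adjusted p = 6.54e-12, and 0.0121 with an estimated correlation), with Nop56 up 1.80-fold, Nolc1 1.71-fold and Myc 1.55-fold. Of 23 HIF targets 8 rose and 1 fell (12 and 1 adjusted over the list alone), with Adm up 2.42-fold and the glucose transporter Slc2a1 1.88-fold (camera adjusted p = 0.00039; adjusted p = 0.556 with an estimated correlation). The cAMP and CREB list had 7 of 20 rising and 1 falling (8 and 2 adjusted over the list alone, camera adjusted p = 0.0428; adjusted p = 0.145 with an estimated correlation), with Atf3 up 3.92-fold. In cholesterol synthesis 8 of 25 rose and 1 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0428; adjusted p = 0.581 with an estimated correlation). The cholesterol call ended in 11 of its alternatives, median-of-ratios scaling and leaving out FD replicate 1 or 3 or FDI replicate 2 or 3 among them, and the cAMP call without FD replicate 1 or 3 or FDI replicate 3, with a pseudocount of 0.1 and with a mean TPM of at least 5.

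Of 20 hepatocyte identity genes 5 fell (6 adjusted over the list alone), Hnf4a from 205 ± 2.99 to 178 ± 3.12 TPM (camera adjusted p = 0.0129; adjusted p = 0.581 with an estimated correlation). Mitochondrially encoded mRNAs fell in 3 of 13 cases (7 adjusted over the list alone, camera adjusted p = 4.83e-05; adjusted p = 0.556 with an estimated correlation), and they made up 12.3% ± 1.43 of TPM in FDI against 14.4% ± 1.10 in FD. The hepatocyte call ended without FD replicate 1 or FDI replicate 2, and the mitochondrial call with quantile normalization. The call of Hnf4a itself ended in a fit of only the 2 groups compared. Median-of-ratios scaling gave 5 mitochondrially encoded mRNAs that fell and quantile normalization 0. Arg1 fell from 88.2 ± 7.58 to 26.9 ± 2.04 TPM, and Mt2 rose 1.53-fold. The Kupffer cell, endothelial, stellate and cholangiocyte marker lists had camera adjusted p = 0.681, 0.900, 0.900 and 0.155, and Sox9, of the last, rose 2.38-fold. Of 21 insulin signalling genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, median −0.07, mean 0.11, direction down, camera adjusted p = 0.900). The glucocorticoid receptor list had a median of 0.07, a mean of −0.24 and the direction down, and 3 rather than 5 of its genes rose with quantile normalization. Signs also differed between median, mean and direction in the unfolded protein response, metal, NRF2, interferon, proliferation, Kupffer cell and endothelial lists, none of which passed camera.

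Insulin left 1172 genes higher and 502 lower than FD alone, of which 68 and 50 changed at least 2-fold, and 30.8% of genes had non-overlapping replicates against 10% by chance. Fitted on the 2 groups alone the counts were 681 and 304, without FDI replicate 3 the higher count was 735, without FDI replicate 1 the lower count was 321, and with FD replicate 3 as the only FD library they were 448 and 176 and the calls of Hnf4a and Mt2 ended. Lower genes were 30.0% of the calls on TPM, 45.1% with median-of-ratios scaling and 46.5% with quantile normalization.

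The direct comparison of FDMn with FDI tested where these groups differ, which they do in agent and in length of exposure. Igfbp1 differed most, at 278 ± 7.33 TPM with manganese and 25.2 ± 3.60 TPM with insulin (log2 change 3.42 ± 0.12, adjusted p = 2.1e-08, n = 3 each). G6pc was 3.06-fold and Pck1 1.46-fold higher with manganese (adjusted p = 7.2e-05 and 0.0038). These were the only 2 higher among the 16 gluconeogenic genes, and 6 were lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.2885). With median-of-ratios scaling 4 were lower. Tat differed by a log2 change of 0.11 ± 0.11 (adjusted p = 0.53). Irs2 (10.4 ± 0.32 TPM with manganese), Fasn, at 18.5 ± 1.88 against 29.9 ± 1.96 TPM, and Ppargc1a (adjusted p = 0.01, 0.0075 and 0.049) were lower with manganese. The Pck1 call ended with a pseudocount of 0.1, and the Ppargc1a call in 17 of its alternatives, among them every one that left out an FDMn replicate.

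Cnn1, Myl9, Acta1, Actc1, Ankrd1 and Fhl2 were the 6 lowest with manganese. Cnn1 stood at 1.84 ± 0.494 against 19.3 ± 3.13 TPM and Ankrd1 at 4.65 ± 0.827 against 23.2 ± 0.982 TPM. The 6 highest were Igfbp1, Lce1d, Serpina3c, Emp1, Serpina3m and Nrg4, of which the Serpina3 genes form a family of close copies. Of 21 FOXO targets 7 were higher and 4 lower with manganese (9 and 4 adjusted over the list alone, camera adjusted p = 0.00445; adjusted p = 0.232 with an estimated correlation). Of 20 integrated stress response genes 14 were lower (15, with 1 that was higher, adjusted over the list alone; camera adjusted p = 4.45e-08; adjusted p = 0.15 with an estimated correlation), Chac1 at 26.7 ± 1.53 against 73.7 ± 6.91 TPM. Of 21 ribosome biogenesis genes 12 were lower (16 adjusted over the list alone, camera adjusted p = 1.28e-06; adjusted p = 0.0937 with an estimated correlation). That count was 7 with median-of-ratios scaling and 7 with quantile normalization, and the lower FOXO count was 2 with median-of-ratios scaling. Of 22 acute phase genes 11 were higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 3.38e-09; adjusted p = 0.0937 with an estimated correlation), the fibrinogen genes Fga, Fgb and Fgg by 1.95-fold, 2.12-fold and 1.73-fold.

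Of 20 cAMP and CREB targets 10 were lower and 3 higher with manganese (11 and 3 adjusted over the list alone, camera adjusted p = 0.0286; adjusted p = 0.15 with an estimated correlation), Nr4a1 at 4.12 ± 0.535 against 15.4 ± 0.796 TPM. This call ended with FD replicate 3 as the only FD library. Of 23 HIF targets 10 were lower and 2 higher (10 and 3 adjusted over the list alone, camera adjusted p = 0.0495; adjusted p = 0.524 with an estimated correlation), with 4 higher under quantile normalization. Of 19 unfolded protein response genes 8 were lower (10, with 2 that were higher, adjusted over the list alone; camera adjusted p = 0.00865; adjusted p = 0.161 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 7 were higher (camera adjusted p = 6.35e-06; adjusted p = 0.271 with an estimated correlation), and their share of TPM in FDI was 12.3% ± 1.43, against 14.7% to 15.5% in the FDMn libraries. Quantile normalization ended this call, with 3 genes higher, and that of the unfolded protein response list, with 5 lower, and the HIF call ended in 10 of its alternatives, among them those without FD replicate 2, FDI replicate 1 or 3, or FDMn replicate 1. Of 22 interferon genes 7 were higher and 1 lower (camera adjusted p = 0.000754; adjusted p = 0.325 with an estimated correlation), and of 20 hepatocyte identity genes 7 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.00329; adjusted p = 0.335 with an estimated correlation). Of 11 proliferation genes 4 were lower (camera adjusted p = 0.044; adjusted p = 0.161 with an estimated correlation), a call that ended in 6 of its alternatives, among them those without FD replicate 1 or FDI replicate 1 and with 1 FD library. Of 7 Kupffer cell genes 1, Cd68, was higher (camera adjusted p = 0.0495; adjusted p = 0.271 with an estimated correlation), and that list call ended in 15 of its alternatives. The stellate list had 2 of 5 genes lower, a median of 0.16, a mean of −0.44 and the direction down (camera adjusted p = 0.231). Arg1, Cps1, Tdo2 and Sgk1 were 2.42-fold, 2.29-fold, 2.78-fold and 2.31-fold higher with manganese. The first 3 were the only higher genes among 23 of amino acid catabolism and the urea cycle. In that list 8 were lower (4 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.9387). Of 21 glucocorticoid receptor targets, which include Sgk1, 3 were higher and 7 lower (4 and 8 adjusted over the list alone, camera adjusted p = 0.6233). Hmox1 stood at 75.6 ± 7.29 against 244 ± 37.6 TPM, and Tfrc and Hamp were 2.23-fold and 2.91-fold higher.

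With manganese 656 genes were higher and 1375 lower than with insulin, of which 56 and 83 differed at least 2-fold; 40.5% of genes had non-overlapping replicates against 10% by chance. The higher count was 1001 with sample quality weights, 437 without FDI replicate 1, 433 without FDI replicate 2, 425 without FDMn replicate 1 and 404 without FDMn replicate 2, and the lower count was 909 with quantile normalization. Lower genes were 67.7% of the calls on TPM, 55.1% with median-of-ratios scaling, 51.6% with quantile normalization and 56.7% without mitochondrially encoded genes.

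The genes that FD moved at least 2-fold were then followed. Of the 370 FD-raised genes, 133 (35.9%) fell with manganese and 22 rose further, and 86 (23.2%) fell with insulin and 43 rose further; 56 fell with both. Of the 429 FD-lowered genes, 121 (28.2%) rose with manganese and 19 fell further, and 135 (31.5%) rose with insulin (87 with median-of-ratios scaling) and 10 fell further; 74 rose with both. Simulated libraries with no effect of manganese or insulin gave at most 1 gene in each of these 4 opposite-direction counts, a value near 0 by construction that does not measure a tilt among genes that change. Among all genes tested 1172 were higher and 502 lower with insulin, and 834 and 912 with manganese. A lean towards rising with insulin is thus not particular to the FD-lowered genes, while the FD-raised genes leaned the other way. In the direct comparison 94 FD-raised genes were lower and 43 higher with manganese than with insulin. Of the FD-lowered genes 73 were lower and 38 higher. Among all genes called in that comparison 67.7% were lower, a share that moved with scaling. The FD-raised and FD-lowered genes leaned the same way as all genes. These counts therefore do not show that manganese opposed the FD response more than insulin did. With no group given manganese or insulin alone, a reversal cannot be told apart from a change that either agent makes by itself. When 1 FD library defined the response and the other 2 served the comparison, 99 to 109 raised genes fell and 19 to 39 rose with manganese, and 71 to 82 fell and 33 to 55 rose with insulin. Of the lowered genes, 89 to 103 rose and 16 to 28 fell with manganese, and 115 to 120 rose and 10 to 26 fell with insulin. With FD replicate 3 as the only FD library the 4 opposite-direction counts were 55, 56, 58 and 81.

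Across the 11544 genes the manganese and insulin changes correlated with r = 0.516, where simulated libraries with no effect, sharing the FD libraries, gave 0.630 (0.579 to 0.668); genes are not independent replicates. The covariance was 0.0574 against 0.0223 simulated, a difference of 0.0351. With different FD libraries in the 2 changes the covariance averaged 0.0303 over 6 assignments, from 0.0199 to 0.0355, and r averaged 0.212, from 0.145 to 0.250. The 6 reuse the same libraries and are not independent. The covariance was 0.0199 and 0.0228 with FD replicate 3 alone in 1 change, and 0.0340 to 0.0355 with FD replicate 1 or 2 alone. The last range has FD replicates 1 and 2 on opposite sides, so a deviation that they share is not removed. In both effects 329 genes were higher and 204 lower, where independent lists would share 84.7 and 39.7. Simulated libraries with no effect gave at most 1, a value near 0 by construction because hardly any gene is called. Independent lists take no account of the shared FD libraries, and part of the excess may come from those libraries. Neither value therefore shows how much of the overlap is common to the 2 agents. In opposite directions, 9 genes were higher with manganese and lower with insulin, and 45 lower with manganese and higher with insulin.

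**Figure D4:**
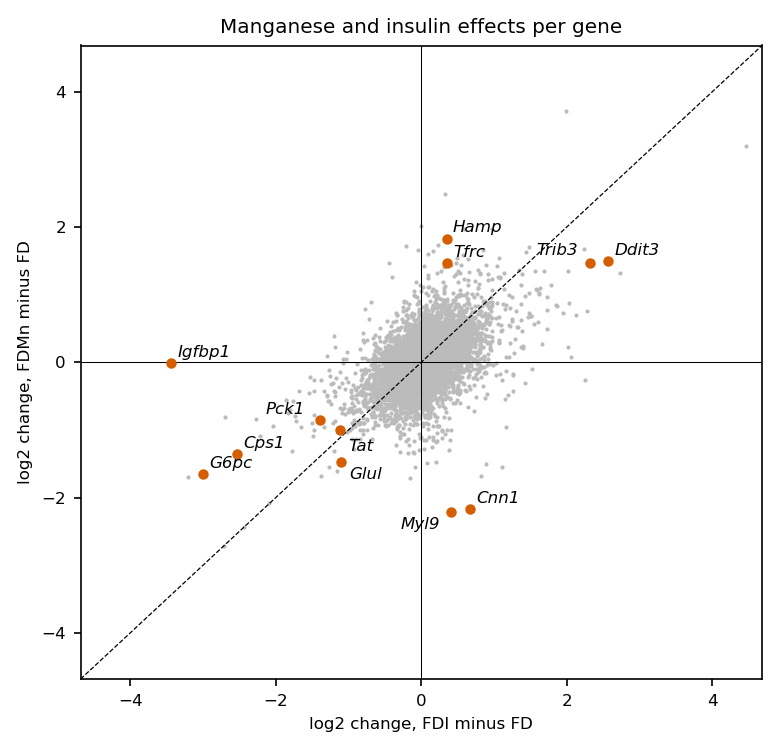
Log2 change per gene with insulin (horizontal axis, FDI minus FD) and with manganese (vertical axis, FDMn minus FD), both on log2(TPM + 1); grey points are the 11544 genes tested, orange points are named genes and the dashed line marks equal change. Igfbp1 lies at −3.44 with insulin and −0.01 with manganese, and Myl9 at 0.40 and −2.22.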

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

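Sample quality weights and the fit with FD replicate 3 as the only FD library were chosen after seeing the data; every other alternative was planned. Of 47 list calls 34, and of 372 calls of named genes 305, passed under each alternative run, and none was reversed. Most named genes were taken for a small adjusted p or a large change, which favours such calls. The camera test with an estimated correlation is not among these alternatives. With it no list passed for manganese (lowest adjusted p = 0.0812) or for FDMn and FDI (lowest adjusted p = 0.0937). With median-of-ratios scaling FD and Mock differed in 2054 higher and 1982 lower genes, and 87 FD-lowered genes rose with insulin. Quantile normalization gave 2178 lower genes in FD than in Mock and 909 in FDMn than in FDI. A fit of only the 2 groups compared gave 681 higher and 304 lower genes for insulin, but 779 and 1606 for FDMn and FDI. The main fit used 1 estimate of the spread per gene for all groups. The median residual SD on the log2 scale was 0.1495 in FD, 0.1259 in Mock, 0.1143 in FDI and 0.1028 in FDMn. Quality weights gave 1001 genes higher in FDMn than in FDI. With 1 FD library the counts were 293 higher and 338 lower with manganese, 448 and 176 with insulin, and 55 and 56 FD-raised genes fell and 58 and 81 FD-lowered genes rose with manganese and insulin; that library is assumed to vary like the other groups. With no minimum fold for FD genes the last 4 counts were 302, 221, 496 and 717. Leaving out single libraries gave 475 to 1007 higher and 540 to 1021 lower genes with manganese, 735 to 1440 and 321 to 680 with insulin, and 404 to 718 higher in FDMn than in FDI. The cause of these moves was not tested. The correlation of the manganese and insulin changes stayed within its jackknife SE of 0.113 where both changes used the same FD libraries, and was 0.145 to 0.250 with different ones. With the replicate number as a block the counts were 1279 higher and 3381 lower for FD and Mock, 757 and 826 for manganese, 1039 and 452 for insulin, and 584 and 1245 for FDMn and FDI, and the reversal counts 121, 83, 120 and 132. Same-numbered libraries did not deviate together (18 pairs, r from −0.098 to 0.068), and 5 of the 12 libraries correlated best with their own number. The depth of the libraries is unknown, so what it limits cannot be stated.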

Other observations

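The tests of the FD libraries that stand apart and of the shared FD libraries, the contractile gene set and the split of the FD libraries were chosen only after the result was seen.

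Most genes in a contractile set, chosen after its values were seen and given no list test, were lower with manganese. Of 14 measured, 10 fell against FD (median log2 change −1.13) and 12 were lower than with insulin. Tpm2 went from 276 TPM in FD to 115 TPM in FDMn, Mylk, a myosin kinase, from 8.23 to 2.31 TPM and Flna from 170.4 to 112 TPM, while Vcl rose (log2 change 0.33) and Myh9 had 219 against 215 TPM (adjusted p = 0.837). Tpm1 and Actn1 did not pass either (adjusted p = 0.090 and 0.25). With insulin 8 of the 14 rose (median 0.36), and in FD 10 were lower than in Mock (median −0.43). Actin genes are near-identical in sequence, so Acta1, Acta2 and Actc1 are less certain than the rest.

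Fewer stellate cells or fibroblasts in the manganese cultures could lower contractile genes. The 5 matrix and stellate genes with a TPM of at least 1 had a median log2 change of −0.0178, with an interquartile half-width of 0.072, where that explanation needed −0.564 or lower. Most of them are low, and the highest mean among Col1a1, Col1a2 and Col3a1 was 0.389 TPM. The median is the value of Reln, at a mean of 1.11 TPM. Vim, the abundant member at 181 TPM, fell slightly with manganese (log2 change −0.19, adjusted p = 0.045). So few expressed markers say little about the number of stellate cells. FD libraries that stand apart could also give the pattern. A first form of this test, FDMn against FDI (median −1.38), was left undecided because genes of the set were picked from that comparison, and it was replaced by FDMn against Mock with that value already known. Against Mock, with no FD library involved, the contractile median was −1.40 (half-width 0.57 over genes), beyond a bound of −0.5. Of the 14 genes, 12 had their lowest group mean in FDMn (Cnn1 27.3, Myl9 17.4 and Tagln 44.9 TPM in Mock). The contractile values in FDMn were thus low without reference to any FD library. The test cannot decide, because the set was picked on the same FDMn libraries. FDMn also differs from Mock in forskolin and dexamethasone, and FD against Mock already had a median of −0.43, near the bound. FD libraries that stand apart stay open as a part of the cause, and an effect of manganese stays open as a hypothesis.

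More genes were lower than higher in FD than in Mock. TPM is a share, so a rise in abundant transcripts may shift most genes down together. With median-of-ratios scaling lower genes were 49.1% of the calls, but that scaling centres the typical gene by construction, so the share decides nothing. A shift from TPM scaling and a fall of many transcripts in the cells cannot be told apart here.

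FD-raised genes were lower with manganese and with insulin. A chance excess in the shared FD libraries could give such a pattern. The planned test, a count above those simulated with no effect, decides nothing because such counts are near 0 whatever the cause, and it was replaced with the values of the split FD libraries already known. With no library shared between the response and the comparison, raised genes that fell outnumbered those that rose by at least 70 with manganese and 27 with insulin in 3 assignments, which argues against shared libraries as the whole cause. A deviation common to all 3 FD libraries, and an effect of each treatment, stay open.

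Splits of 3 libraries against 3 number 10, too few for a share under 0.05. The real split called 4743 genes for FD and Mock, 1746 for manganese, 1674 for insulin and 2031 for FDMn and FDI, and was the 1 split with as many in each case. The other splits called at most 2 genes. Each of them mixes both groups on each side, which puts the group difference into the spread. Counts near 0 are therefore built in, and the contrast with the real split decides nothing.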
